A study of Homo sapiens with 8 samples.

How the data were processed

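Gene expression was measured on 8 Illumina HumanRef-8 bead arrays, each hybridised with RNA from 1 culture. There were 4 arrays of IMR90 (diploid fibroblasts from lung), 2 arrays of BJ (diploid fibroblasts from foreskin) and 2 arrays of the embryonic kidney line 293, which carries adenoviral sequences. IMR90 cells carried green fluorescent protein (GFP) as a control, the catalytic subunit of human telomerase (hTERT), the SV40 large T antigen, or large T with oncogenic H-Ras and hTERT. BJ cells carried an empty lentiviral vector or the same 3 factors. The labels give BJ the catalogue number of IMR90, so the identity of BJ rests on the titles and the labelled tissue. The kidney pair was a 293 culture with the empty vector and a culture titled 293T with Ras and hTERT. The labels give 293 as the source of that culture and call it a fibroblast. The line 293T is 293 with large T added, so this pair may hold a difference between the lines beside that of Ras and hTERT. The lentiviral cultures were selected with antibiotics for 5 days, per the labels.

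The authors deposited, per the file headers, the mean signal intensity of each probe over its beads, the standard error of that intensity, the number of beads and a detection p-value against the negative control probes of the array. The deposited intensities were checked to be neither background-subtracted nor normalized between arrays. A second deposited table holds array statistics such as the mean of each class of control probe. The authors' processed table holds log2 values. Of its 18189 probes, 15412 equalled the log2 of the same probe's deposited signal to within 0.001 on every array, and 2777 did not. Of the 2777, 1726 equalled the log2 of the linear mean of that probe and 1 of the 3995 probes outside the table. GenomeStudio 2010.2, RMA and Partek are named in the submitters' processing notes. The versions of RMA and Partek, and the role of each tool, are not given in the sources used here.

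Values were computed from the deposited signal with R 4.3.3 and limma 3.58.1. The neqc function corrected the background with a normal-exponential model fitted from the detection p-values, added an offset of 16, normalized the 8 arrays together by quantiles and took log2. Of the 22184 probes, 16425 were paired with 1 gene symbol, 0 with several and 5759 with none. An Entrez identifier was found for 16407 of them, and 0 symbols were replaced by newer ones. The 16425 probes gave 16327 genes, of which 89 had more than 1 probe. A gene was represented by the probe with the highest mean over the 8 arrays. A gene entered a comparison when its detection p was under 0.01 on at least 1 of the arrays compared.

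Each pair of arrays was described by the log2 difference of each gene and by the number of genes at least 2-fold higher or lower. With 1 array per condition no p-value was computed for a pair. For a gene detected on only 1 array of a pair, a lower bound on the fold was computed. The bound is the value on the array that detected it minus the higher of the other array's value and that array's floor, the lowest normalized value among its detected probes. The combination of 3 factors was tested across IMR90 and BJ with limma on 4 arrays. The model held the line as a block, which pairs each transformed culture with the control of its own line. This left 1 residual degree of freedom, and limma's prior had 5.03 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

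The comparisons, the alternatives, the rule for naming genes and 26 gene lists were fixed before the data were examined. The lists had 579 entries, of which 527 were measured. They cover DNA replication, mitosis, p53 targets, the Ras-ERK response, extracellular matrix, the contractile and TGF-beta response, secreted inflammatory factors, matrix proteases and inhibitors, interferon-stimulated genes, the NF-kB response, CDK inhibitors with the RB pathway and Wnt pathway targets and inhibitors. Others cover hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and amino acid stress response, the BCL2 family, homologous recombination with Fanconi anaemia, telomerase and shelterin and the Ras family. The last ones are markers of fibroblasts, epithelium, endothelium, blood and immune cells and the 293 line, positional identity genes, and reference genes. In each pair, the median log2 difference of a list's detected members was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. Its interval came from 2000 bootstrap draws over the members. The medians of these pairs were also computed with members detected on only 1 array at their bound. Those of the hTERT, SV40 and combined IMR90 arrays against the BJ control are given as measured. Across the lines, the lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, and adjusted over the 26 lists.

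Named genes follow a rule. For the combination in each fibroblast line and for hTERT and SV40 in IMR90, they are the 10 highest and the 10 lowest genes detected on both arrays, with up to 3 per direction by their bound. For the other pairs they are the 5 highest and 5 lowest. Across the lines, where fewer than 20 genes passed, they are the 10 highest and 10 lowest by the smaller of the absolute log2 differences of the lines. Up to 4 members per list were named by the size of their difference, and HRAS was read on all arrays. Genes used to check the identity of samples are not reported here.

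The alternatives were no background correction, an offset of 50, scaling each array to the same median, the authors' processed values, the lines normalized apart, 3 other filters on detection, the mean over the probes of a gene, other fold thresholds, and for the limma test other models and samples. Scaling to the 75th percentile, and the BJ control array as the reference for IMR90, were added after the data were seen. Array-wide shifts were read over 7 scalings, the one used for the reported values included. They are not independent, since several share quantile normalization. Median and 75th percentile scaling give the same values relative to the median gene.

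The limma test was tested on simulated data, 20 sets of 8442 genes in which 200 were changed. It recovered 0.70% of genes changed by a log2 of 1, 9.2% at 2, 49.5% at 3 and 75.5% at 4. The mean share of false calls was 8.41%, above the nominal level. The number of arrays limits the precision of every value. Probes with no gene symbol here entered no comparison of genes. The bead standard errors served in the simulations of shared-control correlations, which used 100 sets, and as the tolerance for single genes between alternatives. They hold no variation between cultures.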

Results

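Transcript levels were read on 8 bead arrays, with 1 array per condition and therefore no replicates. The labels give 4 cultures of IMR90 lung fibroblasts, 2 cultures of BJ foreskin fibroblasts and 2 cultures of embryonic kidney cells. They also give BJ the catalogue number of IMR90, and the 293T array the source of 293, so the lines are named here by the array titles. The number of arrays limits the precision of every value, and differences between pairs of arrays are given as measured, without p-values. Of the 22184 probes, the IMR90 GFP control detected 7812, the fewest of the 8 arrays. The IMR90 hTERT array detected 10200, the IMR90 SV40 array 8365 and the IMR90 array with Ras, SV40 large T and hTERT, called the combined array from here on, 8540. The BJ control vector array detected 9335 and the BJ combined array 9519. The 293 control detected 10230 and the 293T Ras and hTERT array 10752. The mean signal intensity was 468 on the GFP control, 873 on the hTERT array, 499 on the SV40 array and 467 on the IMR90 combined array. It was 656 and 768 on the BJ control and combined arrays, and 750.5 and 830 on the 293 and 293T arrays. The means of the negative controls lay between 166 and 188.

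HRAS, which encodes the introduced GTPase, was not higher on the arrays that carried Ras. Relative to the median gene, its log2 difference from control over the scalings was -1.22 to -0.45 for IMR90, -0.94 to -0.64 for 293T and -0.33 to -0.21 for BJ. Its log2 value was 9.34 on the IMR90 GFP control, 8.58 with hTERT, 8.79 with SV40 and 8.12 on the combined array. In BJ it was 8.63 on the control and 8.29 on the combined array, and in the kidney cells 9.99 on the 293 control and 9.06 on the 293T array. Where the probe lies relative to the introduced sequence is unknown, so these values neither show nor exclude the transgene. TERT was not analysed here.

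Quantile normalization gives every array the same distribution, and other scalings moved the median over all genes. Scaled to the same median, the log2 difference of the median gene was 0.97 for hTERT against GFP, -0.89 for the IMR90 combined array against hTERT, -0.49 for the GFP control against the BJ control and 0.17 for BJ combined against control. The authors' values gave 0.94, -0.80, -0.48 and 0.23 for the same pairs, and 0.13, 0.17 and 0.11 for IMR90 combined against GFP, SV40 against GFP and 293T against 293. Scaling to the 75th percentile gave -0.16 for IMR90 combined, -0.18 for hTERT and -0.17 for SV40 against GFP, and 0.15 for GFP against the BJ control. List medians are given after quantile normalization, and their ranges relative to the median gene where a scaling moved it.

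The first comparison asks what the combination of Ras, large T and hTERT changes in IMR90. The combined array had far more transcript of EGR1, an immediate early transcription factor, and of the inflammatory cytokines IL1B and IL6. Genes that copy DNA and divide cells were higher. Genes of the contractile apparatus, cholesterol synthesis and many histones were lower. EGR1 was higher by a log2 of 5.38. IL1B was at least 44.2-fold higher and IL6 at least 34.0-fold higher, since the GFP control detected neither. STMN3, a microtubule-destabilising protein, was higher by 4.24, the glycolytic enzyme ENO2 by 4.17, the lipid carrier APOE by 4.14 and the mitotic topoisomerase TOP2A by 4.01. PHGDH and ASNS, enzymes of serine and asparagine synthesis, were higher by 3.94 and 3.71. The secreted hormone STC1 was higher by 3.78, the stress-induced TOR inhibitor DDIT4 by 3.73 and the antigen-presenting HLA-B by 3.71. OLFML2A, a matrix-binding protein, was at least 19.7-fold higher.

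On the lower side of the IMR90 combination, the secreted protease inhibitor WFDC1 had a log2 difference of -4.92 and the linker histone H1-2 one of -4.12. The single-stranded DNA binding protein NABP1 was at -3.84, the membrane protein TMEM98 at -3.74, and the histones H2AC18 and H2BC21 at -3.70 and -3.45. LRRC17, a secreted regulator of bone cells, was at -3.66, the keratin-associated KRTAP1-1 at -3.65, the microfibril protein FBN2 at -3.45 and the cancer-testis antigen CTAG2 at -3.43. CCND2, the cyclin D2 that drives entry into S phase, was at least 32.2-fold lower. The vasoconstrictor EDN1 was at least 29.4-fold lower and the respiratory chain subunit COX7A1 at least 25.2-fold lower.

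Of 7381 genes detected in this IMR90 pair, 1365 were at least 2-fold higher and 1106 at least 2-fold lower. The higher genes were 55.2% of these, and 41.5% after scaling to the 75th percentile. Among genes detected on both arrays, 614 were higher and 734 lower. Counts of list members are of those at least 2-fold apart, as measured and then with members detected on 1 array at their bound. Of 26 detected mitosis genes 26 were higher as measured and 19 with bounds, with a median log2 difference of 2.56, or 1.69 with bounds. Among them NUSAP1, a spindle protein, was at least 12.4-fold higher, and the kinases AURKB and CDK1 were at least 8.74-fold and 8.28-fold higher. Of 28 DNA replication genes 25 were higher, 21 with bounds, with a median of 2.52, or 1.93 with bounds, and the helicase subunit MCM5 was at least 5.65-fold higher. Secreted inflammatory factors had a median of 3.26, or 2.00 with bounds, with 12 of 16 higher, 11 with bounds. The prostaglandin synthase PTGS2 was at least 11.4-fold higher. NF-kB response genes had a median of 2.63, or 1.92 with bounds, with 8 of 9 higher, 7 with bounds, among them the inhibitor NFKBIA at 2.97.

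In the same pair, 10 of 15 contractile and TGF-beta response genes were lower, with a median of -1.43, or -1.36 with bounds, and calponin CNN1 was at -2.96. Cholesterol synthesis genes had a median of -1.76, or -1.49 with bounds, but of -0.50 against the BJ control, since the GFP control lay at 1.11. Of 13 members 9 were lower than with GFP, and the sterol enzymes SC5D and MSMO1 were at -3.01 and -2.69. Relative to the median gene, the medians over all scalings ranged from 1.11 to 2.56 for mitosis, from 1.18 to 3.26 for secreted factors, from -1.43 to -0.90 for contractile genes and from -1.77 to -0.68 for cholesterol synthesis. Extracellular matrix genes had a median of 0.30 that changed sign, to -0.20, under scaling to the 75th percentile, and relative to the median gene it ranged from -0.04 to 0.30. Within that list the collagens COL6A2 and COL6A1 were higher by 2.46 and 2.08, while the proteoglycan LUM was at -2.87. The hypoxia and glycolysis median was 0.65, or 0.55 with bounds, with ALDOC higher by 3.33 and the glucose transporter SLC2A1 at -2.65. Reference genes had a larger median in this pair, 0.80, with 5 of 11 higher and 0 lower. The GFP control detected the fewest probes of any array, and only 614 of the 1365 higher genes were detected on both arrays. The count of the others rests on values as measured on an array that did not detect them, not on bounds.

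The same combination was compared in BJ, to ask which changes occur in a fibroblast line of another origin. The BJ combined array had much more transcript of IL11, a cytokine of the IL6 family, and of TFPI2, an inhibitor of serine proteases. Other higher genes encode further cytokines and proteins of the Ras-ERK response. The collagens COL3A1 and COL1A1 were lower, as were ALDH1A1 and IGFBP3. IL11 was higher by 6.22, TFPI2 by 5.36 and CDCP1, a surface protein phosphorylated by SRC kinases, by 4.94. The cytokine IL24 was higher by 4.40, the tetraspanin-like TM4SF1 by 4.33, the Ras-induced membrane protein TMEM158 by 4.32 and the cornified envelope protein LCE2A by 4.28. The urokinase gene PLAU was higher by 4.17, the growth factor NRG1 by 3.97 and PTGS2 by 3.90. ANGPTL4, which inhibits lipoprotein lipase, was at least 32.6-fold higher, IL1A at least 20.4-fold and the neutrophil chemokine CXCL5 at least 19.2-fold.

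ALDH1A1, a retinaldehyde dehydrogenase, had the lowest log2 difference in BJ at -5.98. The growth factor binding protein IGFBP3 was at -5.08, the heparan sulfatase SULF1 at -4.49 and the oxytocin receptor OXTR at -4.32. ID2 and ID3, inhibitors of differentiation factors, were at -4.07 and -3.40. STMN2 was at -3.95, the mitochondrial protein EFHD1 at -3.84, C1QTNF5 at -3.67 and the proteoglycan GPC1 at -3.29. The keratin KRT19 was at least 17.1-fold lower, the matrix protein SBSPON at least 16.5-fold and WFDC1 at least 14.8-fold.

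Of 8074 genes in the BJ pair, 809 were at least 2-fold higher and 634 lower, and among genes detected on both arrays 489 and 460. The higher genes were 56.1%, against 69.5% after median scaling and 80.6% in the authors' values. Secreted inflammatory factors had a median of 2.51, or 2.29 with bounds, and 16 of 21 were higher, 15 with bounds. Mitosis genes had a median of 1.88 with 29 of 31 higher, 25 with bounds, among them the spindle regulator ASPM by 2.73. DNA replication genes had a median of 1.83, or 1.67 with bounds, and 28 of 32 were higher, 26 with bounds. Ras-ERK response genes had a median of 1.47, or 1.20 with bounds, with 14 of 22 higher, 12 with bounds, EGR1 by 3.68 and IER3 by 3.17. Extracellular matrix genes had a median of -1.29, or -1.17 with bounds, with 15 of 24 lower and 3 higher with bounds, COL3A1 at -3.07 and COL1A1 at -3.01. Contractile genes had a median of -1.17 with 9 of 16 lower, such as ACTA2 at -1.77, but the smooth muscle actin ACTG2 was higher by 3.23. The p53 target median was -0.47, with ZMAT3 at -1.89 and PHLDA3 at -1.84. Relative to the median gene, the ranges over scalings were 2.06 to 2.52 for secreted factors, 1.29 to 1.93 for mitosis, -1.35 to -1.01 for matrix, -1.25 to -0.92 for contractile genes and -0.46 to -0.26 for p53 targets.

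**Figure D1:**
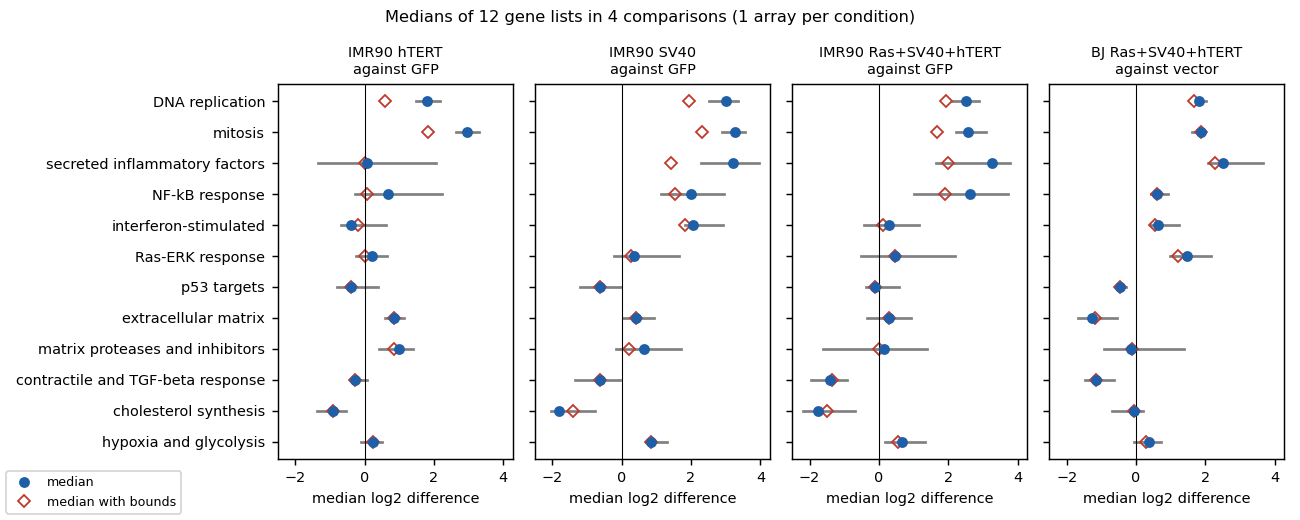
Median log2 difference (horizontal axis) of 12 gene lists in 4 comparisons, 1 array per condition: circles are medians, grey bars bootstrap intervals over members, and diamonds medians with members detected on 1 array at their bound. Mitosis medians lie between 1.88 and 3.27 in the 4 panels; relative to the median gene, sign changes between scalings occur in the hTERT panel for secreted factors, the Ras-ERK response and hypoxia, in the IMR90 combined panel for matrix and proteases, and in the BJ panel for proteases.

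Across IMR90 and BJ together, the combination was tested with limma, taking each line as a block. CDCP1, the neuronal ligand DNER, PTGS2, the exonuclease ISG20 and the cytokine LIF were higher in both lines. WFDC1, the carboxypeptidase CPA4 and the thyroid hormone deiodinase DIO2 were lower in both. The formaldehyde-metabolising ADH5 also read lower in both, on a probe that read below the negative controls on both combined arrays. No gene of 8442 passed, with 0 calls and a smallest adjusted p of 0.143. At an unadjusted p under 0.05 there were 867 genes, of which 532 were higher and 335 lower, where chance alone would give 422.1. Median scaling called 12 genes, the authors' values called 2, and the genes detected on every array gave 3 calls, while the other limma alternatives called 0. The authors' values called ADH5 and IL1B, and the restriction to every array called TFPI2, EGR1 and STC1. Median scaling called each of these and also DNER, WFDC1, PTGS2, CDCP1, IL24, ISG20 and LIF.

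By log2 fold change over both lines, TFPI2 was at 4.52 (adjusted p 0.154), EGR1 at 4.53 (adjusted p 0.154) and both were detected on all 4 arrays. CDCP1 was at least 8.22-fold higher in IMR90 and higher by 4.94 in BJ. DNER was at least 10.6-fold higher in IMR90 and at least 7.29-fold in BJ. PTGS2 was at least 11.4-fold higher in IMR90, ISG20 at least 3.06-fold and 7.20-fold in the respective lines, and LIF at least 3.35-fold and 6.88-fold. IL1B was higher by 3.67 in BJ, IL24 by 4.40 there and at least 5.82-fold in IMR90, and the chemokine CCL20 at least 2.62-fold in IMR90 and 8.70-fold in BJ. WFDC1 was at -4.92 in IMR90 and at least 14.8-fold lower in BJ. ADH5 read at least 3.41-fold and 3.78-fold lower in IMR90 and BJ. Its probe read below the negative controls on both combined arrays and on the 293 control. The normalized ADH5 value was the same on both combined arrays, 4.42, and its log2 fold change in the authors' values was -4.85. Such readings cannot be taken as a level of transcript, so the ADH5 difference and calls may not be ones of expression. The heat shock protein CRYAB was at -2.90, the protease PRSS23 at -2.38, the PI3K regulator PIK3IP1 at -2.33 and the coatomer subunit COPZ2 at -2.38, each detected on all 4 arrays, with adjusted p between 0.226 and 0.227. CPA4 was at -3.04 in IMR90 and at least 4.10-fold lower in BJ. DIO2 was at least 2.48-fold and 4.44-fold lower in the respective lines. The thrombin receptor F2RL2 and the arrestin-like ARRDC4 were at -2.34 and -2.26 in BJ and at least 2.66-fold and 4.70-fold lower in IMR90.

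**Figure D2:**
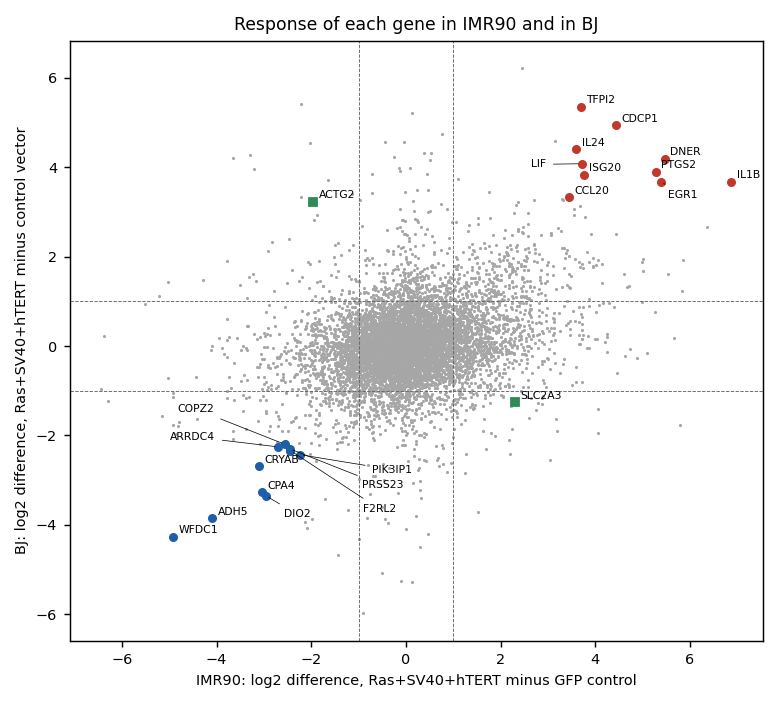
Log2 difference of each gene in IMR90 (horizontal axis) and BJ (vertical axis), combined minus control array, with dashed lines at 2-fold; red and blue points are the named genes highest and lowest in both lines and green squares are named genes at least 2-fold apart in opposite directions. The Pearson correlation across the 8442 genes is 0.283, and ACTG2 and SLC2A3 lie in opposite quadrants.

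The IMR90 and BJ responses had a Pearson correlation of 0.283 and a Spearman correlation of 0.248 across genes, which are not independent replicates. Their signs were the same for 58.3% of genes. Across the 5607 genes detected on all 4 arrays, the correlations were 0.260 and 0.206. In both lines 353 genes were at least 2-fold higher, where independent responses would share 138, and 194 were at least 2-fold lower, against 88.5. In opposite directions there were 146 genes, 75 of them higher in IMR90 and 71 higher in BJ, against 108 and 113.

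In the list tests across both lines, camera with the preset correlation called 13 of 26 lists, and 0 of these calls held with the estimated correlation, where the smallest adjusted p was 0.652. That version rests on the 1 residual degree of freedom of the fit. Secreted factors and contractile genes had estimated correlations of -0.048 and -0.05, below the preset one, and still lost their calls. Its 0 calls therefore cannot tell whether correlation between members undoes the preset calls. Fry, which tests whether a list moves on balance one way, also called 0, with a smallest adjusted p of 0.132. No member of any list passed over all genes. The counts below are adjusted over the list alone, and the medians in this paragraph hold their sign under all 7 scalings. Mitosis genes had a median log2 fold change of 2.15, or 1.66 with bounds, and 29 of 31 passed (camera adjusted p 2.43e-27, adjusted p = 0.652 with an estimated correlation). DNA replication genes had a median of 2.12, or 1.58 with bounds, and 27 of 32 passed (camera 1.80e-25). Secreted inflammatory factors had a median of 2.34, or 1.99 with bounds, and 11 of 22 passed (camera 1.49e-12). Homologous recombination and Fanconi genes had a median of 1.60, or 0.63 with bounds, and a camera value of 4.12e-09, but 0 of 11 were detected on all 4 arrays, so this call rests on values near background. Of the mitosis, DNA replication and secreted lists, 8, 11 and 7 members were detected on all 4 arrays, and no count of passing members was made with bounds. Contractile genes had a median of -1.001 with 6 of 16 passing (camera 1.71e-06), and Ras-ERK response genes one of 0.78 with 5 of 23 passing (camera 6.15e-06). In IMR90 alone the Ras-ERK median was 0.48 (bootstrap -0.52 to 2.18), with 8 higher and 4 lower, against 1.47 in BJ with 0 lower. NF-kB response genes had a median of 1.10, or 0.79 with bounds, with 1 of 11 passing (camera 0.000116), and were at 2.63 in IMR90 and 0.62 in BJ.

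The other lists called by camera across both lines had larger adjusted camera p-values, and their medians also hold their sign under all 7 scalings. Cholesterol synthesis was at -0.80 with 0 of 15 passing over the list alone (camera 0.00635), hypoxia and glycolysis at 0.52 with 0 of 21 (camera 0.0108) and fibroblast markers at -0.61 with 1 of 16 (camera 0.0162). Interferon-stimulated genes were at 0.35 with 2 of 22 (camera 0.0176), the Ras family at -0.78 with 1 of 3 (camera 0.0236) and extracellular matrix at -0.58 with 2 of 24, 1 of them higher (camera 0.0495, adjusted p = 0.687 with an estimated correlation). Within IMR90 alone the matrix median flips under scaling to the 75th percentile. Within BJ alone the cholesterol synthesis median was -0.07, and -0.05 to -0.03 relative to the median gene. Not called were CDK inhibitors with the RB pathway at 0.69, with 0 of 16 past the list alone, blood and immune markers at 0.68 with 0 of 5, epithelial markers at -1.04 with 0 of 4, 293 markers at -0.65 with 0 of 6, positional identity at -0.20 with 0 of 11 and reference genes at 0.31 with 0 of 11. Also not called were p53 targets at -0.30 with 0 of 21, the unfolded protein response at 0.10 with 0 of 18, the BCL2 family at -0.15 with 0 of 11 and telomerase and shelterin at -0.19 with 0 of 11. These medians flip between scalings as measured, and hold their sign relative to the median gene. The last medians flip either way. Endothelial markers were at 0.04 with 0 of 4. Matrix proteases had a median of -0.09, a mean of 0.01, a downward camera test and an upward fry test, and 4 of 19 passed over the list alone, 2 of them higher. Wnt targets had a median of 0.05 and a mean of -0.29 with a downward test, and 1 of 9 passed.

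The next comparison asks what hTERT alone changes in IMR90. Telomeres were not measured here, so effects of telomerase at telomeres and outside them cannot be told apart. Genes of cell division were higher with hTERT than with GFP, led by PRC1, which bundles spindle microtubules. Genes for the matrix proteins MXRA5 and collagen VI were higher too. CTAG2, CCND2 and the monocyte chemokine CCL2 were among the lowest. PRC1 was higher by 3.69, TOP2A by 3.30, MXRA5 by 3.28, EGR1 by 3.25 and TFPI2 by 2.86. The cyclins CCNA2 and CCNB2 were each higher by 2.83, thymidine kinase TK1 by 2.80, the centromere protein CENPM by 2.74 and the anaphase activator CDC20 by 2.64. The cytokinesis protein ANLN was at least 8.53-fold higher, CLDN11 at least 8.05-fold and the proteoglycan SPOCK1 at least 7.92-fold. CTAG2 was at -4.21, CCND2 at -4.19, the endosomal NSG1 at -3.92, the transcription factor NPAS1 at -3.73 and the scavenger receptor OLR1 at -3.68. The methyltransferase INMT was at -3.36, CCL2 at -3.11, the histones H4C8 and H2AC18 at -3.07 each and the elongation factor EEF1A2 at -3.05. COX7A1 was at least 38.7-fold lower, the kinase ligand ALKAL1 at least 38.1-fold and the cystatin CST1 at least 11.0-fold.

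Of 8195 genes in the hTERT pair, 1033 were at least 2-fold higher and 473 lower, 68.6% higher. Among genes detected on both arrays the balance turns, with 260 higher and 362 lower. The share over all these genes depends on the scaling, at 97.8% after median scaling, 35.8% after scaling to the 75th percentile and 99.5% in the authors' values. Of 31 detected mitosis genes 31 were higher as measured and 25 with bounds, with a median of 2.96, or 1.82 with bounds, and 1.42 to 2.91 relative to the median gene over the scalings. KIF20A, a cytokinesis motor, was at least 7.15-fold higher and AURKB at least 7.82-fold. Of 30 DNA replication genes 27 were higher as measured and 13 with bounds, with a median of 1.80, or 0.58 with bounds. Extracellular matrix genes had a median of 0.86, with 8 of 23 higher, and 0.58 to 0.84 relative to the median gene, but of 0.10 against the BJ control. Matrix proteases had a median of 1.00, or 0.84 with bounds, with 9 of 18 higher, 8 with bounds, among them MMP3 by 2.20. Against the BJ control in place of GFP, the matrix protease median of the hTERT array turns to -0.35. Cholesterol synthesis genes had a median of -0.91, and -0.96 to -0.56 relative to the median gene, but against the BJ control it turns to 0.17, since the GFP control lay at 1.11. MSMO1 was at -2.30 and SC5D at -1.71. The shelterin gene TERF1 was at -0.38 and the telomerase and shelterin median of -0.05 flips between scalings, from -0.24 to 0.07 relative to the median gene. The hTERT array was the brightest and the GFP control among the dimmest of the 8, so counts by direction carry that difference.

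Large T alone was compared with GFP in IMR90 to ask what the viral antigen does without the other factors. Inflammatory and interferon-stimulated genes were higher than with GFP, as were genes of cell division. Enzymes of sterol synthesis and CCND2 were lower. TFPI2 was higher by 5.00, PRC1 by 4.11, the chemokine CXCL1 by 4.09, the interferon-induced membrane protein IFITM1 by 3.88 and the transcription factor TCF21 by 3.87. STC1 was higher by 3.86, EGR1 and TOP2A by 3.85 each, the replication clamp partner PCLAF by 3.56 and CDC20 by 3.54. IL6 was at least 61.3-fold higher, IL1B at least 31.3-fold and the collagen COL15A1 at least 15.7-fold. COX7A1 was at -3.51, MSMO1 at -3.50, the dynein light chain DYNLT3 at -3.29, SC5D at -3.26 and the neuronal LRRN3 at -3.17. EDN1 was at -3.09, CTAG2 at -3.03, the ion channel ANO4 at -2.98, the junction protein TMEM47 at -2.97 and the opsin OPN3 at -2.86. CCND2 was at least 30.5-fold lower, ALKAL1 at least 23.5-fold and CPA4 at least 17.6-fold.

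Of 7162 genes in the SV40 pair, 1005 were at least 2-fold higher and 754 lower, and among genes detected on both arrays the balance turns, with 436 higher and 486 lower. The higher share over all these genes was 57.1%, against 76.8% in the authors' values and 46.6% after scaling to the 75th percentile. Of 28 mitosis genes 28 were higher as measured and 25 with bounds, with a median of 3.27, or 2.32 with bounds. Of 29 DNA replication genes 28 were higher, 27 with bounds, with a median of 3.02, or 1.95 with bounds. Interferon-stimulated genes had a median of 2.04, or 1.81 with bounds, with 16 of 19 higher, 12 with bounds, among them IFI27 at least 6.68-fold and OAS3 at least 5.37-fold. Against the BJ control in place of GFP, the interferon-stimulated median of the SV40 array was 0.10, since the GFP control itself lay at -2.10. Secreted inflammatory factors had a median of 3.21, or 1.41 with bounds, with 15 of 18 higher, 11 with bounds. NF-kB response genes had a median of 2.01, or 1.53 with bounds, with 8 of 9 higher, 7 with bounds. Homologous recombination genes had a median of 2.64, or 0.79 with bounds, but 11 of 11 members were detected on only 1 array of the pair. With bounds, 4 were higher and 0 lower. Cholesterol synthesis genes had a median of -1.82, or -1.40 with bounds, with 9 of 13 lower, 8 with bounds, but of -0.80 against the BJ control. Reference genes had a median of 0.51 with 4 of 11 higher and 0 lower. Of 17 p53 targets 7 were lower, 6 with bounds, with a median of -0.64, ZMAT3 at -2.20 and the nucleotide reductase RRM2B at -2.13. Relative to the median gene, the ranges over scalings were 1.48 to 3.32 for mitosis, 1.15 to 2.10 for interferon-stimulated genes, -1.77 to -0.63 for cholesterol synthesis and -0.58 to -0.22 for p53 targets.

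Adding Ras and hTERT to large T was read from the IMR90 combined array against the SV40 array. Interferon-stimulated genes and matrix proteases were lower on the combined array, and several p53 targets were higher. EEF1A2 was higher by 3.83, ASNS by 3.31, DNER by 3.30, the elongation factor TCEA3 by 3.08 and the immediate early gene FOS by 2.84. WFDC1 was at -4.24, the antiviral GTPase MX1 at -3.42, TMEM98 at -3.36, the growth factor BMP2 at -3.33 and the steroid enzyme HSD17B2 at -3.31. Of 7298 genes 533 were at least 2-fold higher and 503 lower, 51.4% higher, against 29.7% in the authors' values. Among genes detected on both arrays the balance turns, with 273 higher and 288 lower. Interferon-stimulated genes had a median of -1.67, or -1.44 with bounds, with 12 of 18 lower, 10 with bounds, and a range of -1.67 to -0.99 over the scalings. IFIT2 was at least 10.6-fold lower and IFI27 at least 8.41-fold. Matrix proteases had a median of -1.07, or -0.64 with bounds, with 8 of 15 lower, 7 with bounds, such as the collagenase MMP1 at -3.11 and the aggrecanase relative ADAMTS1 at -3.05. The p53 target median was 0.75, or 0.51 with bounds, with 7 of 20 higher, 5 with bounds, RRM2B by 1.95 and ZMAT3 by 1.76. The mitosis median was -0.52 and that of DNA replication -0.40, and neither flips under a scaling. Ras-ERK response genes had a median of -0.15, with 1 of 20 higher and 2 lower with bounds. Secreted inflammatory factors were at -0.18, with 0 of 18 higher and 4 lower with bounds, and NF-kB response genes at -0.08. Against the BJ control, the Ras-ERK median was 0.43 on the GFP control, 0.48 with hTERT, 0.49 with SV40 and 0.45 on the IMR90 combined array.

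Adding Ras and large T to hTERT was read from the IMR90 combined array against the hTERT array. Secreted inflammatory factors were higher and fibroblast markers lower. EEF1A2 was higher by 5.65, the cytochrome CYP1B1 by 4.54, IL6 by 4.30, complement factor CFB by 4.21 and TCEA3 by 3.95. IL1B was at least 85.5-fold higher. ADAMTS1 was at -4.25, the pentraxin NPTX1 at -3.95, the Wnt inhibitor DKK1 at -3.67, FBN2 at -3.59 and MMP1 at -3.56. Of 8335 genes 814 were at least 2-fold higher and 1075 lower, so 43.1% were higher, against 7.48% after median scaling, 56.0% after scaling to the 75th percentile and 1.63% in the authors' values. Among genes detected on both arrays the balance turns, with 610 higher and 492 lower. Secreted inflammatory factors had a median of 2.81, or 2.30 with bounds, with 13 of 16 higher, 12 with bounds, and 1.53 to 2.87 relative to the median gene. NF-kB response genes had a median of 1.35, or 1.25 with bounds. Fibroblast markers had a median of -1.24, or -0.91 with bounds, with 9 of 15 lower, 7 with bounds, CD248 at -2.77 and the receptor PDGFRA at -2.59. Contractile genes had a median of -1.24, or -1.11 with bounds. DNA replication had a median of 0.70 and mitosis one of -0.32, or -0.20 with bounds. Relative to the median gene they ranged from 0.35 to 0.77 and from -0.36 to -0.16.

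The IMR90 responses to hTERT, SV40 and the combination share the GFP control, so part of any correlation between them may come from that array. Across 8467 genes the Pearson correlation was 0.688 between hTERT and SV40, 0.605 between hTERT and the combination and 0.791 between SV40 and the combination. Simulated unchanged arrays with bead error against the same control gave 0.582, 0.594 and 0.546. The covariance minus the simulated one was 0.563, 0.575 and 0.932. The simulation holds bead error only and no variation between cultures, which the shared control also carries into each response. Responses with no array in common had a correlation of 0.0197 for hTERT minus GFP against combined minus SV40, and 0.383 for SV40 minus GFP against combined minus hTERT. Genes at least 2-fold higher in both numbered 616 for hTERT and SV40, 605 for hTERT and the combination and 829 for SV40 and the combination. Those lower in both numbered 206, 229 and 570. The shared control adds to these overlaps by an amount that was not estimated. Genes are not independent replicates, and no p-value was computed.

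**Figure D3:**
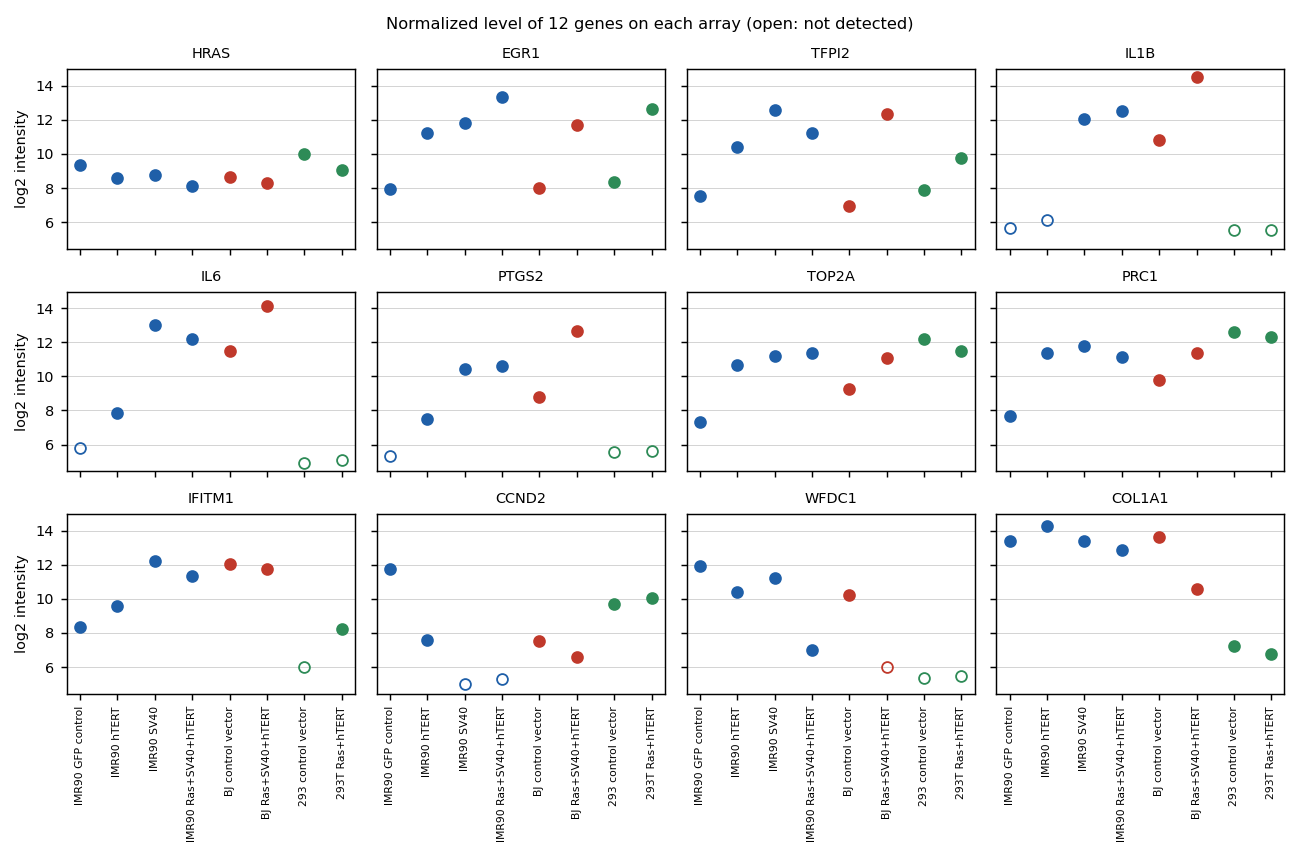
Normalized log2 intensity (vertical axis) of 12 genes on each of the 8 arrays, IMR90 in blue, BJ in red and kidney cells in green, with open circles where the gene was not detected. EGR1 lies between 7.96 and 8.34 on the GFP, BJ and 293 controls and between 11.21 and 13.34 on every other array.

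In the kidney cells, the pair asks what Ras and hTERT change in an epithelial line, with the difference between 293 and 293T in the same contrast. Epithelial genes were lower on the 293T array, led by the keratin KRT19 and the adhesion protein EPCAM. EGR1 and the transcription factor MYC were higher. KRT19 was at least 61.6-fold lower. EPCAM was at -5.06, the actin bundler LCP1 at -4.65, TMEM47 at -4.25, the splicing factor SNU13 at -3.88 and the transport protein MAL2 at -3.61. EGR1 was higher by 4.30, the neurofilament NEFM by 4.14, MYC by 3.92, the globin HBQ1 by 3.81 and the transcription factor HAND1 by 3.80. Of 8938 genes 751 were at least 2-fold higher and 737 lower, 50.5% higher, against 66.1% in the authors' values. Among genes detected on both arrays 496 were higher and 516 lower. Epithelial markers had a median of -2.07, or -1.88 with bounds, with 8 of 10 lower, 6 with bounds. Matrix proteases and inhibitors had a median of 1.78, or 1.47 with bounds, with 7 of 9 higher, 5 with bounds, such as TIMP1 by 2.40. Interferon-stimulated genes had a median of -0.89, or -0.71 with bounds, and p53 targets one of -0.68, with the apoptosis effector BAX at -2.002. Ras-ERK response genes had a median of 0.50, or 0.33 with bounds, and the unfolded protein response one of 0.45, with the transcription factor XBP1 higher by 1.69. None of these medians flips under a scaling, and relative to the median gene the range was -2.23 to -1.17 for epithelial markers and 0.89 to 1.79 for matrix proteases.

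The control arrays of the fibroblast lines give the size of a difference between lines and vectors. The IMR90 GFP control had more ACTG2, HOXB5 and HOXB7 than the BJ control, and less of the interferon-stimulated and mitosis genes. ACTG2 was higher by 6.39, the bradykinin receptor BDKRB1 by 5.00, TM4SF1 by 4.94, CCND2 by 4.21 and the costimulatory ligand TNFSF4 by 3.57. HOXB5 was at least 59.8-fold higher and HOXB7 at least 11.1-fold. The calcium-binding S100A4 was at -5.23, MXRA5 at -4.73, MMP3 at -4.69 and the pregnancy-specific glycoproteins PSG5 and PSG11 at -4.54 and -3.98. The cathepsin CTSK was at least 102-fold lower, the thrombospondin THBS2 at least 46.0-fold and the endopeptidase MME at least 37.0-fold. Of 7627 genes 492 were at least 2-fold higher and 909 lower, so 35.1% were higher, against 11.8% after median scaling, 52.8% after scaling to the 75th percentile and 7.33% in the authors' values. Among genes detected on both arrays the balance turns, with 329 higher and 283 lower. Mitosis genes had a median of -1.49, or -0.67 with bounds, with 22 of 25 lower as measured and 10 with bounds. Interferon-stimulated genes had a median of -2.10, or -1.35 with bounds, with 15 of 19 lower, 12 with bounds, and secreted inflammatory factors one of -2.23, or -1.08 with bounds, with 10 of 15 lower, 8 with bounds. Over the 7 secreted factors detected on both arrays the median turns to 0.11. Cholesterol synthesis had a median of 1.11 and positional identity one of 1.96. Relative to the median gene, the ranges over scalings were -1.50 to -0.31 for mitosis, -2.11 to -0.98 for interferon-stimulated genes, -2.24 to -1.19 for secreted factors and 0.56 to 1.10 for cholesterol synthesis. Read against the BJ control, the mitosis median was 1.51 on the hTERT array, 1.89 on the SV40 array and 1.20 on the IMR90 combined array. The interferon-stimulated median was -1.97, 0.10 and -1.34 on the same arrays, that of secreted factors -1.44, 1.32 and 1.06, and that of matrix proteases -0.35, -0.78 and -1.43. The DNA replication median was 0.97, 2.01 and 1.51, that of the NF-kB response -0.54, 1.03 and 0.94, that of cholesterol synthesis 0.17, -0.80 and -0.50 and that of matrix 0.10, -0.21 and -0.20.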

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

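The 7 tests of explanations in this part were chosen after the results were seen. With 1 array per condition, none of the differences between IMR90 and BJ given here was tested.

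Several responses to the combination ran in opposite directions in IMR90 and BJ. ACTG2, a smooth muscle actin, was at -1.96 in IMR90 and higher by 3.23 in BJ, a difference of -5.19, and neither direction flips over the 7 scalings. Its level in the controls also differed, by 6.39 between the lines. SLC2A3, a glucose transporter, was higher by 2.29 in IMR90 and at -1.26 in BJ, a difference of 3.56, and again neither direction flips. In all 146 genes were at least 2-fold apart in opposite directions. Of these, 75 were higher in IMR90 and lower in BJ, where independent responses would give 108, and 71 the reverse, where they would give 113.

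Probes with no gene symbol here entered none of the comparisons of genes. Of 5759 such probes 2229 were detected, and 70 were at least 2-fold higher on both combined fibroblast arrays, where independent responses would share 29.3. Another 51 were at least 2-fold lower on both.

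Extracellular matrix genes had a median of 0.30 in IMR90, which flips to -0.20 under scaling to the 75th percentile, and of -1.29 in BJ, a difference of 1.59. Array brightness is argued against as the whole cause, since the smallest difference over the scalings, with bounds, was 1.08. A low matrix level in the GFP control might hide lower values in IMR90: against the other IMR90 arrays the combined array was at -0.15 (SV40, bootstrap -0.49 to 0.25) and -0.30 (hTERT, bootstrap -0.74 to -0.03). These intervals are over list members within single pairs of arrays and hold no variation between cultures, so they cannot decide the explanation. The hTERT array was itself at 0.86 for matrix against GFP. Against the BJ control the GFP control was at -0.30, or -0.26 with bounds, and at 0.08 under scaling to the 75th percentile. The explanation stays open. A difference between the lines in their response was not tested and stays open too.

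Mitosis genes were higher than in the GFP control on all 3 other IMR90 arrays, hTERT alone included. Brightness is argued against as the whole cause, since the lowest median relative to all genes, with bounds, was 1.03. A low level in the GFP culture could contribute: its median against the BJ control was -0.67 with bounds and -1.49 without, but 17 of 25 members were detected on only 1 of these arrays and the lines differ. The introduced factors may instead raise these genes above the level of a control fibroblast, since the lowest of the 3 medians against the BJ control was 1.20. The GFP control and the line cannot be told apart with 1 control array per line, so both remain open.

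Interferon-stimulated genes were lower on the IMR90 combined array than on the SV40 array, at a median of -1.44 with bounds. Brightness is argued against, since the highest median relative to all genes over the scalings was -0.88. A candidate explanation is that Ras with hTERT lowers these genes: in the kidney pair, 12 members had a median of -0.71 with bounds (bootstrap -0.99 to -0.36), the direction this explanation calls for, though it was written down only after the result. The BJ combined array, which carries Ras and hTERT with large T, was above its control, with a median of 0.62, or 0.54 with bounds. With bounds, 8 members were higher and 0 lower. The like IMR90 contrast, combined against GFP, was also above 0, at 0.29 or 0.13 with bounds, with 3 higher and 1 lower with bounds. Combined against hTERT was at 0.36, with 4 higher and 0 lower with bounds, and hTERT against GFP at -0.38, or -0.20 with bounds. Against the BJ control, the SV40 array was the highest of the IMR90 arrays, at 0.10. The GFP, hTERT and combined arrays were at -2.10, -1.97 and -1.34. BJ has no array with large T alone to match the contrast with SV40. The kidney pair also holds the difference between 293 and 293T, BJ also holds large T, and variation between single cultures was not measured, so this explanation stays open.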

How the results depend on the processing

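Scaling to the 75th percentile and the BJ control as a reference for IMR90 were chosen after the data were seen; the other alternatives were planned. For the genes with the largest differences that were rerun, 585 values stayed within 2 bead standard errors of the reported one. Another 255 moved further with the same sign and 0 changed sign. Genes across the lines were read in each line alone, within 1 limma standard error. The detection filters leave a gene's value as it was by construction. So does the mean over probes, except for the 89 genes with more than 1 probe. The genes were chosen for large differences, or for the same direction in both lines, so the absence of sign changes was largely fixed beforehand. Of the recomputed medians of lists that stood out from random gene sets, 854 stayed within the bootstrap interval of the reported one, 126 left it with the same sign and 30 changed sign. Where no cause is given below, the cause was not tested.

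Without background correction the genes at least 2-fold apart numbered 1166 for IMR90 combined, 379 for hTERT and 796 for SV40 against GFP, 573 for BJ, 332 and 662 for IMR90 combined against SV40 and hTERT, 466 for 293T and 531 for GFP against the BJ control. Uncorrected background compresses differences by construction, as does an offset of 50, which gave 957 for hTERT. Median scaling gave 4018 for hTERT against GFP and 3957 for IMR90 combined against hTERT, where the median of all genes lay at 0.97 and -0.89. The authors' values gave 895 for IMR90 combined, 3720 for hTERT, 672 for SV40, 775 for BJ, 222 and 3196 for IMR90 combined against SV40 and hTERT, and 576 for 293T. Requiring detection on every array, which tests fewer genes, gave 1348 for IMR90 combined, 622 for hTERT, 922 for SV40, 949 for BJ, 561 and 1102 for IMR90 combined against SV40 and hTERT, and 612 for GFP against the BJ control. In the order IMR90 combined, BJ, hTERT, SV40, combined against SV40, combined against hTERT, 293T and GFP against BJ, a 1.5-fold threshold gave 4044, 3107, 3167, 3241, 2510, 3866, 3424 and 2777 genes, and a 3-fold threshold gave 1247, 549, 528, 866, 362, 716, 486 and 649. With the BJ control as reference the counts, 2267 for IMR90 combined, 1278 for hTERT and 1780 for SV40, stayed within 1.5 times the reported ones. The GFP and BJ controls alone differed at 1401 genes, so like counts do not show that the same genes changed. The hTERT array differed at fewer genes from the BJ control than from its own GFP control, where the count was 1506.

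The correlation of the IMR90 and BJ responses stayed within its interval. Median and 75th percentile scaling differ by a shift per array and so give identical correlations: hTERT correlated at 0.602 with SV40, 0.496 with the combination and -0.0352 with combined minus SV40. The authors' values gave 0.505, 0.386 and -0.0738 for the same pairs. Genes detected on every array gave 0.656 and 0.561 for hTERT with SV40 and the combination, and 0.762 for SV40 with the combination.

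The limma test across lines called 12 genes under median scaling, 2 in the authors' values and 3 among genes detected on every array, against 0 in the reported fit and in the other models and filters run. In the reported fit 867 genes had an unadjusted p under 0.05. Without the replicate block that pairs each culture with its line, there were 0 calls and 707 at an unadjusted p under 0.05. Camera called 13 lists, and camera with the estimated correlation and fry each called 0. The estimated correlation rests on 1 residual degree of freedom, so its 0 calls do not decide whether the 13 hold. Leaving out either line leaves 1 array per condition and no test.

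List medians changed sign as follows. Median scaling of hTERT against GFP gave 0.62 for p53 targets, 0.56 for interferon-stimulated genes, 0.16 for cholesterol synthesis, 0.39 for the BCL2 family and 0.34 for the Ras family. For IMR90 combined against hTERT it gave -0.23 for DNA replication, -0.58 for hypoxia and -0.33 for reference genes, and for GFP against the BJ control -0.0649 for the Ras-ERK response. The authors' values gave 0.80, 0.57, 0.36, 0.56 and 0.53 for the same hTERT lists, -0.45, -0.79 and -0.58 for those of IMR90 combined against hTERT, and -0.27 for the Ras-ERK response. The median of all genes moved in both settings, and relative to it each of these lists keeps its reported sign, such as p53 targets at -0.35 and -0.13 and DNA replication at 0.66 and 0.35, though hypoxia in the authors' values is near 0, at 0.00675. These sign changes thus come from the shift of all genes. Scaling to the 75th percentile gave -0.16 for CDK inhibitors and -0.31 for fibroblast markers with hTERT, where the median of all genes lay at -0.18, and 0.0825 for matrix in GFP against the BJ control, where it lay at 0.15. That shift exceeds the CDK inhibitor and matrix values but not that of fibroblast markers. Requiring detection on every array gave -0.16 for CDK inhibitors with hTERT and 0.11 for secreted factors in GFP against the BJ control, with fewer members tested. Without a filter, matrix proteases with SV40 were at -0.0124, and positional identity at 0.0499 in IMR90 combined against hTERT and -0.0572 in GFP against the BJ control. With the BJ control as reference, matrix proteases were at -0.35 and cholesterol synthesis at 0.17 for hTERT, and matrix at -0.21 and matrix proteases at -0.78 for SV40.

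Signal over background limits which genes can be compared. Negative controls had means of 166 to 188 where the median probe read from 194 on the GFP control to 245 on the 293T array, so differences of dim genes are bounds.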

Other observations

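The gene families in this part were chosen after their values were seen, and no explanation was tested for them. Histone genes, which encode the proteins that package DNA, were lower than the GFP control on all 3 other IMR90 arrays. The median log2 difference of 18 detected histone genes on the combined array was -2.86, or -1.61 with bounds, with 15 at least 2-fold lower, 14 with bounds. It was -1.91 on the hTERT array, or -1.78 with bounds, and -1.06 on the SV40 array, or -1.05 with bounds, and none of these medians flips over the 7 scalings. H4C8 was at -3.07 with hTERT and H2AC6 at -2.63 with SV40. The linker histone H1-10 went the other way, higher by at least a log2 of 3.73 on the combined array, 3.02 with SV40 and 1.97 with hTERT. The GFP control was above the BJ control for histones, with a median of 1.13. In BJ the combination gave -0.34, or -0.26 with bounds, and -0.36 to -0.16 relative to the median gene over the scalings.

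Genes of antigen presentation by HLA class I were higher on the SV40 and combined IMR90 arrays, with medians of 0.92 (0.89 with bounds) and 0.80, and these signs hold over the scalings. Of 9 members 4 and 3 were at least 2-fold higher, 3 and 2 with bounds. The GFP control itself had a median of -1.27 against the BJ control, with 5 of 9 lower and HLA-B at -3.73. Reference genes had medians of 0.51 with SV40 and 0.80 on the combined array, where B2M, a member of both sets, is the median gene of each. HLA-B was higher by 3.51 with SV40, 3.71 with the combination and 1.76 with hTERT. The hTERT median of 0.06 for this family flips over the scalings, from -0.07 to 0.14 relative to the median gene. The BJ combined array had a median of -0.34 for the same genes. Metallothioneins, which bind zinc and copper, were higher on the BJ combined array, with a median of 2.35, or 1.69 with bounds, MT1G higher by 2.39 and 4 of 5 members at least 2-fold higher, 3 with bounds. Against their own controls, the metallothionein median was -0.25 on the IMR90 combined array, -1.05 with SV40 in IMR90 and -0.97 in the 293T pair. The GFP control itself had a metallothionein median of 1.56 against the BJ control, with 2 of 3 members at least 2-fold higher. Pregnancy-specific glycoproteins were lower with SV40 in IMR90, at -2.60 or -1.24 with bounds, where 5 of 5 members were detected on only 1 array. They were also lower on the IMR90 combined array, at -1.05 or -1.03 with bounds, and on the BJ combined array, at -1.23. With hTERT they were at -0.99, and -1.13 to -0.47 relative to the median gene over the scalings. The GFP control itself lay at -3.36 against the BJ control, or -2.54 with bounds. Cytosolic ribosomal protein genes had a median of 0.47 over 58 members on the IMR90 combined array against GFP and of 0.38 against SV40, and neither flips over the scalings. Against hTERT it was 0.52, and 0.42 to 0.81 relative to the median gene. None of these family values was tested against variation between cultures.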
